A study of Homo sapiens with 21 samples.

How the data were processed

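RNA of MM.1S, a human multiple myeloma line grown from peripheral blood, was measured by mRNA sequencing in 21 libraries, 3 for each of 7 groups. The groups were untreated cells, cells given pomalidomide at 1 µM and collected after 24, 48 or 72 h, cells labelled control knockdown, and cells transduced for 72 h with lentivirus carrying a hairpin against ARID2 or a hairpin against Aiolos, the protein of IKZF3. The hairpin and the time of the control knockdown are not given in the sources used here. Libraries were made with the TruSeq RNA v2 kit and run on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name the genome build hg38. The aligner, the quantifier, the gene annotation and any filter are not given in the sources used here.

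The authors deposited 1 table in TPM, the length-scaled share of transcripts, with 17691 gene symbols and 1 column per library, and no symbol appeared more than once. TPM divides each gene's reads by its length and scales every library to the same total, so it keeps no record of sequencing depth, and the depth of each library is unknown. The listed genes summed to between 951444 and 968652 TPM per library, so 3.14% to 4.86% of each library's total lies in features not listed here. A TPM value is a share: a gene's TPM can fall because other genes rose. No intervals for counting error can be given without counts.

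Values were analysed as log2(TPM + 1). Genes with at least 1 TPM in at least 3 libraries were kept, which left 12559 genes holding at least 99.9% of the listed TPM of every library. All 21 libraries entered 1 linear model in limma 3.58.1 under R 4.3.3, with the 7 group means as coefficients and empirical Bayes moderation with a trend in mean expression (14 residual and 5.28 prior degrees of freedom). In all, 10 contrasts were taken between the group means, 2 of them differences between a drug effect and the effect of the ARID2 knockdown or of the labelled libraries. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and a gene passed at an adjusted p under 0.05. All adjusted p-values come from limma. Fold changes are given on the log2 scale with their standard errors, and TPM as mean and SD over 3 libraries. The submitters describe the 3 libraries of a group as biological replicates and say nothing of days or cultures, so the p-values measure the spread between these libraries.

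Before the data were examined, the groups, the contrasts, the tests, the 30 gene lists and the rule for naming genes were fixed. The rule names ARID2, IKZF3, IKZF1, MYC, IRF4, CRBN, BRD7 and PBRM1 everywhere. It adds, for the 3 drug times, the ARID2 knockdown and the libraries labelled Aiolos knockdown, the 8 genes with the largest rise and the 8 with the largest fall among genes that passed, whose libraries did not overlap between the groups and whose mean reached 5 TPM in the higher group. Other contrasts take 4 in each direction, and each list that passed gives up to 4 members with the smallest p. For the 2 differences between effects the condition on overlap has no meaning and was not applied. Clone names and near-identical families (SPRR2, LCE1, CCL3 and CCL3L3, SULT1A4) were passed over in the ranking; which families these were was decided when the ranking was seen. Ribosomal protein, HLA, histone, actin, KLRC and HSPA1 genes have close copies, and readthrough genes share exons with their parts, so their values are uncertain where reads could be divided among copies.

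The 30 lists cover the CRBN ligase, CRBN neosubstrates, PBAF subunits, other SWI/SNF subunits, plasma cell transcription factors, MYC targets, interferon-stimulated genes, antigen presentation, myeloma surface proteins, MAF targets, the secretory pathway and unfolded protein response, the integrated stress response, S phase, G2/M, p53 targets with CDK inhibitors, the BCL2 family, NF-kB targets, ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis, immediate early and heat shock genes, replication histones and the cytoskeleton with adhesion. They also cover markers of B cells, T and NK cells, myeloid cells, epithelial and stromal cells and erythroid cells, and mitochondrial mRNA. Lists with at least 3 genes kept by the filter were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data and with fry. The erythroid list kept 2 genes and has no list test. Symbols were matched to GENCODE 29 on GRCh38, the build also called hg38: 17448 matched 1 gene, 17394 of them protein coding, and 243 matched none and were kept under the deposited symbol.

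Fold changes of different contrasts were compared across genes by Pearson r, Spearman rho and covariance, which describe these libraries, since genes are not independent replicates. Libraries with no effect were simulated with the same controls and the fitted spread to give the value of chance. Alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, the libraries of the compared groups alone, no trend, the replicate number as a block, and leaving out each library in turn. A comparison of the ARID2 knockdown and of the libraries labelled Aiolos knockdown with the untreated libraries, also within the 2 differences of effects, and correlations without the cell cycle, MYC target and histone lists, were added after seeing the data.

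The steps were tested on simulated data with 50 genes shifted at each of several sizes. For pomalidomide at 72 h, 29 of 50 genes shifted by 0.25 on the log2 scale were recovered, 42 of 50 at 0.5, and all 50 at 1 and at 2, with 14 unchanged genes called among 12499. For the ARID2 knockdown the numbers were 29, 45, 49 and 50, with 9 unchanged genes called among 12542. For the libraries labelled Aiolos knockdown they were 30, 45, 50 and 50, with 6 called among 12544. The median standard error of a log2 fold change was 0.07. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.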

Results

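The series holds mRNA profiles of MM.1S, a human multiple myeloma line, under the drug pomalidomide and with hairpins against ARID2 or against Aiolos. Pomalidomide binds cereblon (CRBN), the substrate receptor of a ubiquitin ligase, and directs proteins such as Ikaros (IKZF1) and Aiolos (IKZF3) to it for degradation. ARID2 is a subunit of PBAF, a form of the SWI/SNF chromatin remodeller. The design sets the drug beside hairpins against each of the 2 genes. The labels name no untreated cells for each drug time, so time in culture cannot be told apart from time in drug. Each of the 7 groups had 3 libraries: untreated, pomalidomide at 24, 48 and 72 h, control knockdown, ARID2 knockdown, and the libraries labelled Aiolos knockdown. Between 14158 and 15264 genes were above 0 TPM in a library. Within groups the correlation of libraries across genes ran from 0.993 to 0.996 over 21 pairs, and between groups from 0.908 to 0.987 over 189 pairs. No 2 libraries had identical values for more than 0.876% of genes. The highest values belonged to IGLL5, which shares sequence with an immunoglobulin lambda constant gene, and to mitochondrial mRNAs.

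The share of listed TPM in mitochondrial mRNA, a sign of RNA and cell quality, differed between groups. It was 15.5% ± 0.13 in untreated cells (SD, n = 3), 17.0% ± 0.496 at 24 h, 16.7% ± 0.129 at 48 h and 13.7% ± 0.45 at 72 h. In the control knockdown it was 17.2% ± 0.373, in the ARID2 knockdown 18.5% ± 0.24 and in the libraries labelled Aiolos knockdown 15.7% ± 0.838. Ribosomal protein genes held 8.04% ± 0.126 in untreated cells and 7.00% ± 0.128 at 72 h of drug. They held 8.79% ± 0.094 in the control knockdown and 8.68% ± 0.152 in the ARID2 knockdown. Their share was largest in the libraries labelled Aiolos knockdown, at 11.7% ± 0.331.

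The targeted genes were read first. ARID2 lies on chromosome 12 from 45729665 to 45908040 (GRCh38, plus strand). Its libraries stood at 26.0, 25.44 and 25.44 TPM in the control knockdown and at 12.44, 12.22 and 12.06 TPM in the ARID2 knockdown, a fall of -1.01 ± 0.07 on the log2 scale (adjusted p = 8.13e-11). In untreated cells ARID2 was 29.8 ± 2.30 TPM. IKZF3 lies on chromosome 17 from 39757715 to 39864188 (minus strand). Its libraries stood at 83.54, 79.15 and 81.35 TPM in the control knockdown and at 127.28, 121.02 and 141.36 TPM in the libraries labelled Aiolos knockdown. The IKZF3 transcript was thus higher where its label says knockdown, by 0.67 ± 0.05 (adjusted p = 1.92e-10), and the protein was not measured here. It was also higher in the ARID2 knockdown, at 118.16, 118.65 and 121.73 TPM (0.55 ± 0.05, adjusted p = 5.09e-09). In untreated cells it was 98.02, 96.72 and 94.52 TPM. Because the transcript goes against the label, these 3 libraries are called the libraries labelled Aiolos knockdown.

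**Figure D1:**
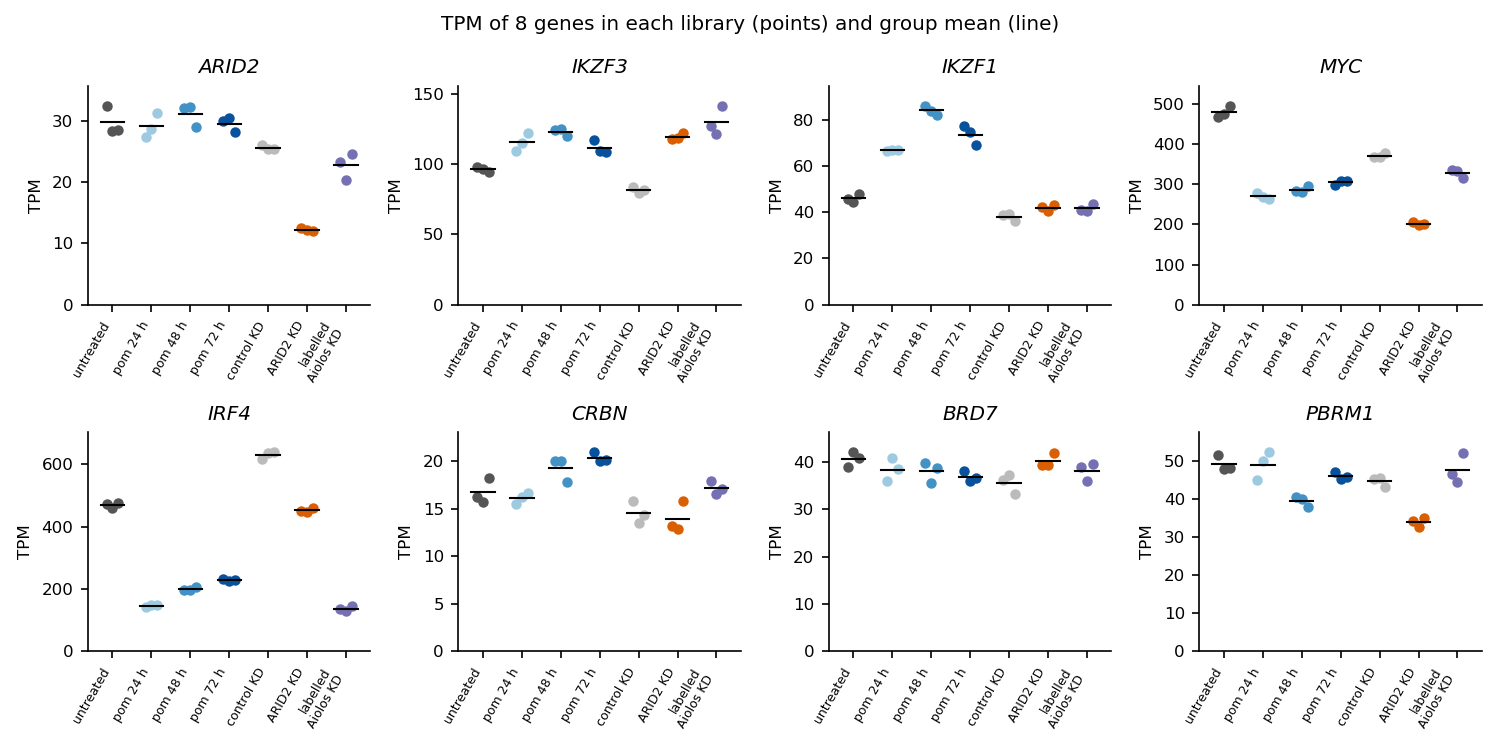
TPM (vertical axes, from 0) of ARID2, IKZF3, IKZF1, MYC, IRF4, CRBN, BRD7 and PBRM1 in the 7 groups, with 1 point per library and a line at each group mean (n = 3). ARID2 was lowest in the ARID2 knockdown (12.2 TPM), and IKZF3 was highest in the libraries labelled Aiolos knockdown (130 TPM).

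The other fixed genes were read next over the drug times. IRF4 and MYC encode transcription factors on which myeloma cells depend. IRF4 (chromosome 6, 391739 to 411447, plus strand) fell from 469 ± 8.66 TPM in untreated cells to 147 ± 3.70 at 24 h, and stood at 199.8 ± 5.53 at 48 h and 229 ± 3.75 at 72 h. Its log2 fold changes were -1.67 ± 0.04, -1.23 ± 0.04 and -1.03 ± 0.04. MYC (chromosome 8, 127735434 to 127741434, plus strand) fell by 0.83, 0.74 and 0.65 at the 3 times (SE 0.03 each). IKZF1 (chromosome 7, 50304068 to 50405101, plus strand) rose by 0.53 ± 0.04, 0.85 ± 0.04 and 0.66 ± 0.04, and IKZF3 by 0.26 ± 0.05, 0.35 ± 0.05 and 0.21 ± 0.05. The rise of IKZF3 at 72 h was lost with median-of-ratios scaling (0.05, adjusted p = 0.331). ARID2 did not pass at 24 h (-0.03 ± 0.07), 48 h (0.06 ± 0.07) or 72 h (-0.01 ± 0.07), though median-of-ratios scaling gave a fall at 72 h of -0.17 (adjusted p = 0.0187).

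CRBN and the PBAF genes BRD7 and PBRM1 changed by small amounts with the drug. CRBN (chromosome 3, 3144628 to 3179727, minus strand) was higher at 72 h by 0.27 ± 0.07 (adjusted p = 0.0028), a call lost with median-of-ratios scaling (0.11, adjusted p = 0.153). At 48 h it was higher by 0.19 ± 0.07 (adjusted p = 0.0237). That call was lost without untreated replicate 1 or 2 (0.175 and 0.153), without replicate 1 or 2 of the 48 h group (0.167 and 0.165), and with median-of-ratios scaling (0.12). PBRM1 (chromosome 3, 52545352 to 52685917, minus strand) fell at 48 h by 0.31 (SE 0.06, adjusted p = 4.97e-05). At 72 h it did not pass (-0.09 ± 0.06), but fell by 0.25 with median-of-ratios scaling and by 0.18 with quantile normalization. BRD7 (chromosome 16, 50313487 to 50368934, minus strand) passed at 72 h alone (-0.14 ± 0.06, adjusted p = 0.0316). Its call was lost without untreated replicate 2 or 3 (-0.11 and -0.13) or without replicate 2 or 3 of the 72 h group (-0.12 and -0.13). With median-of-ratios scaling BRD7 also passed at 24 h (-0.13) and 48 h (-0.17).

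The first comparison asks what changed within 24 h of drug. MME, the surface peptidase CD10 of B cell precursors, rose from 5.34 ± 0.506 TPM to 189.8 ± 8.22 TPM (log2 fold change 4.91 ± 0.08). LAMB3, a laminin chain, rose by 5.04 ± 0.23, and LGALS3BP, a secreted glycoprotein induced by interferon, by 4.69 ± 0.18. P2RY6 (3.90), SERPINH1 (3.78), HSD11B1 (3.66) and the B cell chemokine CXCL13 (3.58) followed. GBP6 was listed at 0 TPM in all 3 untreated libraries and at 15.5 ± 1.28 TPM at 24 h. INSIG1, which holds SREBP in the endoplasmic reticulum, fell the most, from 472 ± 3.81 to 52.9 ± 2.70 TPM (-3.14 ± 0.04). SSBP4 (-3.02), CBLN2 (-2.51), ABHD6 (-2.47), TMEM52 (-2.46) and PVRIG (-2.37) also fell. TMEFF1 (-2.48) and its readthrough MSANTD3-TMEFF1 (-2.33) share exons and are uncertain. Adjusted p-values of these genes were at most 4.52e-05. Of the 12559 genes tested, 8301 passed, 4408 higher and 3893 lower, with 625 at least 2-fold higher and 249 at least 2-fold lower. Which direction held more genes depended on scaling: 3936 were higher and 4433 lower with median-of-ratios scaling, and 3889 and 4226 with quantile normalization. For 8620 genes the 3 libraries of each group did not overlap, against a chance share of 10%.

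At 24 h the lists of DNA replication, growth and sterol synthesis fell while mitotic genes did not move together. Of 50 S phase genes 49 fell and 1 did not pass (median -0.97, adjusted p = 2.16e-23), among them MCM6 (-1.32), PCNA (-1.23) and MCM4 (-1.43). Of 60 G2/M genes 17 rose, 14 fell and 29 did not pass, and 15 rose when adjusted over the list alone. Their median of -0.02 was 0.03 with quantile normalization, and the list did not pass (adjusted p = 0.813). Of 54 MYC targets 52 fell and 2 did not pass (median -0.51, adjusted p = 7.06e-18), with UNG at -1.39 and CDK4 at -0.75. Of 24 cholesterol genes 22 fell and 2 did not pass (median -0.94, adjusted p = 4.67e-14), including FDFT1 (-1.55) and FDPS (-0.90). Of 22 glycolysis genes 18 fell, 2 rose and 2 did not pass (median -0.49, adjusted p = 2.09e-06), with ENO1 at -0.62 and TPI1 at -0.49. Where no second count is given, the count adjusted over the list alone was the same.

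Interferon-stimulated, cytoskeletal and histone genes rose at 24 h. Of 44 interferon-stimulated genes 29 rose, 7 fell and 8 did not pass (median 0.62, adjusted p = 0.000104), with IFIT3 at 2.73 and STAT2 at 0.84. Of 42 cytoskeletal and adhesion genes 28 rose, 3 fell and 11 did not pass (median 0.37, adjusted p = 2.13e-06). Of these CORO1B rose by 3.42 ± 0.08 to 52.5 TPM, MYH9 by 1.14 and ACTG1 by 1.03. Of 14 replication histone genes 12 rose and 2 did not pass (median 0.88, adjusted p = 0.00724), with HIST1H2AC at 1.40. S phase genes fell at the same time and replication was not measured. A rise of this list, here or later, is therefore not read as more replication. Antigen presentation had 16 of 23 genes up, 4 down and 3 not passed (median 0.54, adjusted p = 4.23e-05, but adjusted p = 0.107 with an estimated correlation). HLA-DRA rose from 448 to 1197 TPM, and CD74, the invariant chain, from 1086 to 1870 TPM. Myeloid markers had 7 of 8 genes up and 1 not passed (median 1.05, adjusted p = 0.00495, but adjusted p = 0.113 with an estimated correlation), and that list also did not pass without the filter (adjusted p = 0.124). Of these CD68, a lysosomal protein, rose from 4.74 to 42.9 TPM, whereas CD14 reached 2.55 TPM.

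A few further lists moved at 24 h with smaller medians. The integrated stress list had 14 of 26 genes down, 4 up and 8 not passed (median -0.23, adjusted p = 0.0263, but adjusted p = 0.404 with an estimated correlation). PHGDH (-1.48) and PSAT1 (-1.35), of serine synthesis, fell, and DDIT4, an inhibitor of mTORC1, rose by 1.54. Oxidative phosphorylation had 52 of 73 genes down, 5 up and 16 not passed (54 down when adjusted over the list alone), with a median of -0.27 and an adjusted p of 3.03e-09. That became adjusted p = 0.107 with an estimated correlation. Ribosomal protein genes had 52 of 73 down and 21 not passed (54 down when adjusted over the list alone), a median of -0.13 and an adjusted p of 4.54e-07. That became adjusted p = 0.503 with an estimated correlation and 0.0992 with quantile normalization.

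At 48 h the fall of the cell cycle covered mitosis as well. All 60 G2/M genes fell (median -1.92, adjusted p = 1.95e-25), with BIRC5 going from 115 to 22.7 TPM and CDCA5 from 147 to 26.3 TPM. All 50 S phase genes fell (median -2.52, adjusted p = 1.09e-26), 49 of them at least 2-fold, with TYMS at -2.84 ± 0.03 and MCM6 at -2.69 ± 0.03. All 54 MYC targets fell (median -0.99, adjusted p = 2.30e-19), with UNG at -2.51 and LDHA going from 496 to 123 TPM. Among the largest falls were INSIG1 (-3.76), the desaturase SCD (-3.56), CDC6 (-3.56), MYB (-3.43), E2F1 (-3.33), MCM10 (-3.32) and UHRF1 (-3.24). The largest rises were in LAMB3 (5.99), MME (5.89), HSD11B1 (5.53), LGALS3BP (5.48), SERPINH1 (4.78), CLSTN2 (4.60), MMP9 (4.49) and PCDH12 (4.47). Standard errors of these genes lay between 0.04 and 0.23. In all, 9880 genes passed, 5504 higher and 4376 lower, with 1342 and 1011 at least 2-fold.

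Other lists were read at 48 h. Cytoskeletal genes, which had passed upward at 24 h, had 27 of 42 up, 9 down and 6 not passed, and the list did not pass (median 0.29, adjusted p = 0.0874). Cholesterol genes had 21 of 24 down and 3 not passed (median -1.55, adjusted p = 2.55e-10), and glycolysis 18 of 22 down, 3 up and 1 not passed (median -0.85, adjusted p = 3.74e-06). Oxidative phosphorylation had 65 of 73 down, 3 up and 5 not passed (median -0.55, adjusted p = 1.51e-13). Replication histones had 13 of 14 up and 1 down (median 1.41, adjusted p = 0.00386), with HIST1H2AC rising from 6.10 to 82.9 TPM. Myeloma surface genes had 18 of 23 up, 4 down and 1 not passed (median 0.37, adjusted p = 0.0313, but adjusted p = 0.182 with an estimated correlation). Of these ITGB7 rose from 8739 to 19090 TPM and LY9 by 1.64, while SLAMF7, a target of antibodies in myeloma, fell by 0.87. Antigen presentation had 17 of 23 up, 4 down and 2 not passed (median 0.69, adjusted p = 0.000301, but adjusted p = 0.169 with an estimated correlation). Interferon-stimulated genes had 30 of 44 up, 6 down and 8 not passed (median 0.77, adjusted p = 0.000495, but adjusted p = 0.0615 with an estimated correlation). Myeloid markers had 7 of 8 up, and 8 when adjusted over the list alone (median 1.32, adjusted p = 0.031, but adjusted p = 0.234 with an estimated correlation). Their call was lost without the filter (adjusted p = 0.121) and with the filter of 5 TPM (adjusted p = 0.178). The integrated stress list had 15 of 26 down, 8 up and 3 not passed (median -0.38, adjusted p = 0.0335, but adjusted p = 0.342 with an estimated correlation). Ribosomal protein genes had 60 of 73 down, 3 up and 10 not passed (median -0.26, adjusted p = 5.66e-09, but adjusted p = 0.342 with an estimated correlation).

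At 72 h the falls of dividing-cell genes from untreated cells were deepest. TYMS, thymidylate synthase, fell from 402 ± 6.71 to 24.3 ± 0.622 TPM (-3.99 ± 0.03, adjusted p = 5.71e-26) and RRM2, of ribonucleotide reductase, from 432 ± 1.40 to 22.5 ± 2.77 TPM (-4.21 ± 0.06). MCM10 (-4.13), PBK (-4.12), CENPW (-3.99), PCLAF (-3.98), SHCBP1 (-3.96) and UHRF1 (-3.94) followed. MME reached 369 ± 9.69 TPM (5.87 ± 0.08). HSD11B1 (5.46), LAMB3 (5.36), LGALS3BP (5.22), the gelatinase MMP9 (5.14), the amino acid transporter SLC7A8 (4.83), MYH7B (4.78) and CRYBA2 (4.58) also rose. In all, 10017 genes passed, 6047 higher and 3970 lower (60.4% higher), with 1363 and 980 at least 2-fold. With median-of-ratios scaling 4919 calls were higher and 4925 lower. The median of all genes was 0.15, and that scaling moved it by -0.15 and quantile normalization by -0.10. List medians called relative at 72 h are therefore differences from the median of all genes. Those at 24 and 48 h, in the figures and wherever not called relative are unshifted, so the 2 kinds do not form 1 time course.

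At 72 h all 50 S phase genes fell (relative median -2.99, adjusted p = 1.17e-31), each at least 2-fold. All 60 G2/M genes fell (relative median -3.34, adjusted p = 6.45e-35), with PLK1 going from 116 to 7.82 TPM and TPX2 from 192 to 16.5 TPM. MYC targets had 50 of 54 down, 1 up and 3 not passed (relative median -0.67, adjusted p = 1.47e-13). Cholesterol genes had 20 of 24 down, 1 up and 3 not passed (relative median -1.27, adjusted p = 4.39e-09), with INSIG1 at -3.14. Glycolysis had 17 of 22 down, 3 up and 2 not passed (4 up when adjusted over the list alone; relative median -0.76, adjusted p = 2.70e-05), and LDHA fell from 496 to 132 TPM. Oxidative phosphorylation had 60 of 73 down, 3 up and 10 not passed (relative median -0.64, adjusted p = 1.47e-13, but adjusted p = 0.0509 with an estimated correlation). Interferon-stimulated genes had 30 of 44 up, 10 down and 4 not passed (relative median 0.49, adjusted p = 0.0195, but adjusted p = 0.264 with an estimated correlation), with IFI6 rising from 23.6 to 81.5 TPM. Antigen presentation had 17 of 23 up, 5 down and 1 not passed (relative median 0.47, adjusted p = 0.0047, but adjusted p = 0.339 with an estimated correlation). Ribosomal protein genes had 58 of 73 down, 3 up and 12 not passed (relative median -0.38, adjusted p = 8.13e-10, but adjusted p = 0.485 with an estimated correlation). Mitochondrial mRNAs had 10 of 13 down, 2 up and 1 not passed (relative median -0.40, adjusted p = 0.0195, but adjusted p = 0.612 with an estimated correlation and 0.152 with quantile normalization).

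**Figure D2:**
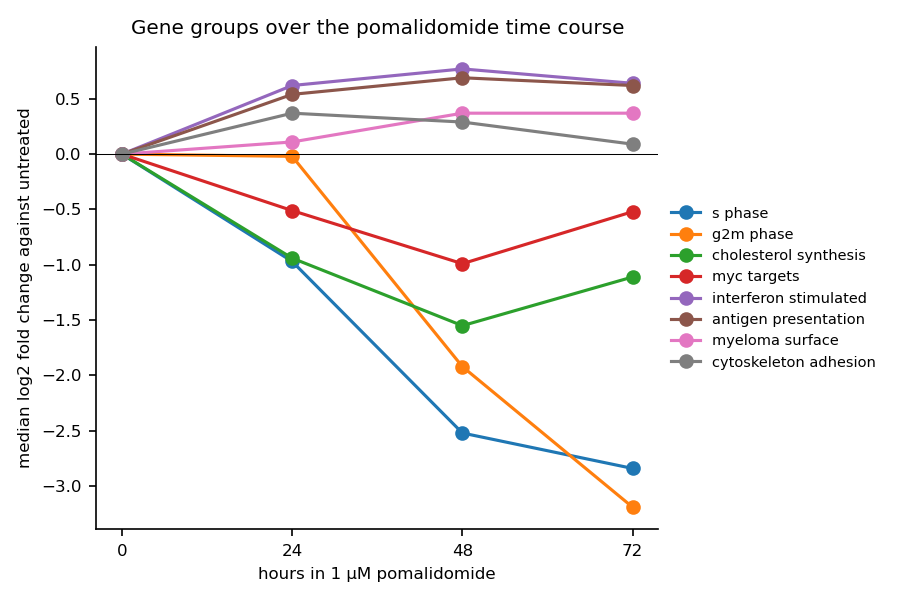
Median log2 fold change against untreated cells (vertical axis) of 8 gene lists at 24, 48 and 72 h of 1 µM pomalidomide (horizontal axis, n = 3 libraries per time), with the untreated level at 0. The G2/M list lay at -0.02 at 24 h (0.03 with quantile normalization) and at -1.92 and -3.19 later, and the S phase list at -0.97, -2.52 and -2.84.

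Lists close to the drug's targets did not pass at 72 h. Of 15 CRBN neosubstrates 11 rose, 2 fell and 2 did not pass (relative median 0.24, adjusted p = 0.187). Of 10 CRBN ligase genes 5 rose, 3 fell and 2 did not pass, with a median of 0.11, a mean of -0.01, a downward test and an adjusted p of 0.805; with median-of-ratios scaling the median was -0.05. Of 4 PBAF genes 2 fell and 2 did not pass (relative median -0.27, adjusted p = 0.387). Of 25 other SWI/SNF genes 10 rose, 11 fell and 4 did not pass, with a median of 0.06, a mean of -0.08 and an adjusted p of 0.617; the median was -0.10 with median-of-ratios scaling. Of 17 plasma cell transcription factors 10 rose, 5 fell and 2 did not pass (relative median 0.15, adjusted p = 0.805). Of 9 MAF targets 4 rose, 3 fell and 2 did not pass (relative median 0.01, adjusted p = 0.672). Of 23 myeloma surface genes 16 rose, 6 fell and 1 did not pass (relative median 0.21, adjusted p = 0.387).

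Stress and death lists were also mixed at 72 h. Of 35 secretory genes 21 rose, 7 fell and 7 did not pass (relative median 0.11, adjusted p = 0.0693), a list that passed with quantile normalization (adjusted p = 0.00479) and without the filter (adjusted p = 0.0223). Of 29 p53 targets and CDK inhibitors 15 rose, 9 fell and 5 did not pass (relative median 0.09, adjusted p = 0.493). Of 32 BCL2 family genes 17 rose, 12 fell and 3 did not pass, and 13 fell when adjusted over the list alone. Their median of 0.12 lay above 0 while camera pointed down (adjusted p = 0.959), and it was -0.05 with median-of-ratios scaling. Of 23 NF-kB targets 12 rose, 7 fell and 4 did not pass (relative median 0.22, adjusted p = 0.542). Of 26 integrated stress genes 12 rose, 9 fell and 5 did not pass (relative median -0.27, adjusted p = 0.509). Of 17 immediate early and heat shock genes 9 rose, 6 fell and 2 did not pass; the median was 0.13, the test pointed down (adjusted p = 0.805), and the median was -0.03 with median-of-ratios scaling. Of 14 histone genes 9 rose, 1 fell and 4 did not pass (relative median 0.61, adjusted p = 0.0693), a list that passed with median-of-ratios scaling (adjusted p = 0.02). Of 42 cytoskeletal genes 19 rose, 16 fell and 7 did not pass (relative median -0.07, adjusted p = 0.734).

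Markers of other cell types were read beside these lists at 72 h. Of 8 myeloid markers 5 rose and 3 did not pass (relative median 0.96, adjusted p = 0.187). Of 5 T and NK cell markers 3 rose and 2 fell (relative median 1.17, adjusted p = 0.71), and of 11 B cell markers 5 rose, 2 fell and 4 did not pass (relative median -0.13, adjusted p = 0.805). Of 6 epithelial and stromal markers 2 rose, 3 fell and 1 did not pass (relative median -0.36, adjusted p = 0.643). Of the 2 erythroid genes EPOR fell from 9.72 to 2.44 TPM (-1.64 ± 0.16), and HBB stood at 13.1 and 12.9 TPM.

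Within the drug series, 72 h was set against 24 h, times without untreated cells of their own. HMOX1, the heme oxygenase induced by oxidative stress, rose from 45.1 ± 2.39 to 508 ± 143 TPM (3.43 ± 0.12), and the heat shock gene HSPA6 (2.71 ± 0.21) and MMP9 (2.64 ± 0.12) also rose. CORO7-PAM16, a readthrough that shares exons with its neighbours and is uncertain, was listed at 0 in all 3 libraries at 24 h and at 6.69 ± 4.40 TPM at 72 h. Mitotic genes fell the most: PLK1 (-3.86), UBE2C (-3.79), DLGAP5 (-3.79) and CDC20 (-3.78). All 60 G2/M genes fell (median -3.16, -3.27 relative to all genes, adjusted p = 1.40e-57), as did all 50 S phase genes (median -1.86, -1.96 relative, adjusted p = 4.19e-42). The cytoskeletal list turned from its rise at 24 h: 25 of 42 genes fell, 10 rose and 7 did not pass (11 rose when adjusted over the list alone; relative median -0.52, adjusted p = 1.02e-06). ACTG1 went from 2909 to 358 TPM and FLNA from 181 to 59.5 TPM. IRF4 rose by 0.64 ± 0.04, and CRBN by 0.32 ± 0.07. Small rises of MYC (0.18 ± 0.03) and IKZF1 (0.14 ± 0.04) depended on scaling, with 0.07 and 0.03 under median-of-ratios (adjusted p = 0.0993 and 0.583), and that of IKZF1 was also lost with quantile normalization (0.04) and without replicate 1 of the 72 h group (0.10). IKZF3 (-0.05 ± 0.05), BRD7 (-0.05 ± 0.06), PBRM1 (-0.09 ± 0.06) and ARID2 (0.02 ± 0.07) did not pass. The first 3 of these passed as falls with median-of-ratios scaling (-0.16, -0.16 and -0.19) and with quantile normalization (-0.13, -0.14 and -0.20), and PBRM1 also without replicate 1 of the 24 h group (-0.15).

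Between 24 and 72 h, 8140 genes passed, 5196 higher and 2944 lower (63.8% higher), or 49.7% higher with median-of-ratios scaling. Mitochondrial mRNAs had 11 of 13 down, 1 up and 1 not passed (relative median -0.43, adjusted p = 3.34e-05, but adjusted p = 0.525 with an estimated correlation and 0.0507 with quantile normalization). Oxidative phosphorylation had 47 of 73 down, 4 up and 22 not passed (5 up when adjusted over the list alone; relative median -0.30, adjusted p = 7.66e-10, but adjusted p = 0.185 with an estimated correlation). Ribosomal protein genes had 41 of 73 down, 9 up and 23 not passed (relative median -0.21, adjusted p = 1.40e-05, but adjusted p = 0.549 with an estimated correlation). Secretory genes had 21 of 35 up, 6 down and 8 not passed (22 up when adjusted over the list alone; relative median 0.06, adjusted p = 0.0389, but adjusted p = 0.525 with an estimated correlation). HERPUD1 (0.99) and DNAJB9 (1.14) rose, yet the list's call was lost with median-of-ratios scaling (adjusted p = 0.215), quantile normalization (0.0553) and the filter of 5 TPM (0.0672). No other list passed.

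The control knockdown was set against untreated cells to read what the control treatment itself brought with it. The integrated stress list rose most: 25 of 26 genes rose and 1 did not pass (median 1.05, adjusted p = 3.38e-30). CHAC1, which degrades glutathione, rose from 5.36 ± 0.118 to 83.6 ± 5.88 TPM (3.73 ± 0.09), PSAT1 from 89.3 to 359 TPM and ATF4 from 465 to 975 TPM. CBS (2.84), ARHGAP9 (2.80) and INHBE (2.71) were the next largest rises. CX3CR1 (-1.43), IER5L (-1.37) and ID3 (-1.26) fell. NEDD8-MDP1, an uncertain readthrough, fell by 1.77 (SE 0.56, adjusted p = 0.0144), a call lost without replicate 2 of the control knockdown (-1.38, adjusted p = 0.082). Of the fixed genes IRF4 rose by 0.43 ± 0.04, while MYC fell by 0.37, IKZF1 by 0.27 and IKZF3 by 0.24. ARID2 was lower by -0.21 ± 0.07 (adjusted p = 0.0163), a call lost without untreated replicate 1 (-0.14). CRBN was lower by -0.19 ± 0.07 (adjusted p = 0.0456), lost without untreated replicate 1 or 3 (-0.21 and -0.13), without control replicate 2 or 3 (-0.14 and -0.18) and under both other scalings. BRD7 was lower by -0.19 ± 0.06 (adjusted p = 0.00887), lost without control replicate 3 (-0.15) and with quantile normalization (-0.13), and PBRM1 did not pass (-0.13 ± 0.06). In all, 5739 genes passed, 2169 higher and 3570 lower, with 88 and 21 at least 2-fold.

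Many lists passed in the control knockdown with small medians. Secretory genes had 30 of 35 up, 2 down and 3 not passed (median 0.28, adjusted p = 1.08e-18), and cholesterol genes 16 of 24 up, 2 down and 6 not passed (median 0.21, adjusted p = 9.75e-06). MYC targets had 51 of 54 down and 3 not passed (median -0.35, adjusted p = 8.98e-17), and S phase genes 33 of 50 down, 1 up and 16 not passed (median -0.23, adjusted p = 7.96e-06). The p53 list had 12 of 29 up, 1 down and 16 not passed (median 0.13, adjusted p = 8.93e-06), led by SESN2 (2.13) and CDKN1A (1.46). SWI/SNF genes had 13 of 25 down, 1 up and 11 not passed (14 down when adjusted over the list alone; median -0.19, adjusted p = 0.00252). Myeloma surface genes had 14 of 23 up, 3 down and 6 not passed (median 0.16, adjusted p = 0.000181), with ICAM1 at 0.98. Histone genes had 6 of 14 up and 8 not passed (median 0.43, adjusted p = 0.00525). Calls lost with an estimated correlation were those of plasma cell transcription factors (8 of 17 up, 4 down; adjusted p = 0.00997, then adjusted p = 0.0728 with an estimated correlation) and of heat shock genes (11 of 17 down, 1 up, 2 up when adjusted over the list alone; adjusted p = 0.00181, then adjusted p = 0.0728 with an estimated correlation). Ribosomal protein genes (41 of 73 up, 43 when adjusted over the list alone, none down; median 0.10) had adjusted p = 0.199 with an estimated correlation, as had mitochondrial mRNAs (11 of 13 up, 12 when adjusted over the list alone, 1 down; median 0.20), which also did not pass with quantile normalization (adjusted p = 0.215). Interferon-stimulated genes had 16 of 44 up and 8 down (17 and 9 when adjusted over the list alone; median 0.05, adjusted p = 0.0108, but adjusted p = 0.149 with an estimated correlation), with a median of -0.01 and adjusted p = 0.0757 under quantile normalization. Antigen presentation had 14 of 23 down and 1 up (median -0.24, adjusted p = 0.0132, but adjusted p = 0.235 with an estimated correlation). Glycolysis had 12 of 22 down and 2 up (13 down when adjusted over the list alone; median -0.15, adjusted p = 0.00401, but adjusted p = 0.108 with an estimated correlation). Oxidative phosphorylation had 28 of 73 down and 7 up (median -0.08, adjusted p = 0.0389, but adjusted p = 0.46 with an estimated correlation), and did not pass with median-of-ratios scaling (0.149) or quantile normalization (0.374).

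The ARID2 knockdown libraries were compared with the control knockdown libraries to read the genes that differ between them. No group is labelled with another hairpin against ARID2 or with ARID2 restored. Effects of lower ARID2 therefore cannot be told apart from other effects of its hairpin. The same limit holds for the hairpin against Aiolos. Targets of p53 led the rises. PHLDA3 rose from 12.7 ± 0.693 to 155 ± 3.13 TPM (3.51 ± 0.09), FDXR from 12.1 ± 0.151 to 124 ± 6.73 TPM (3.26 ± 0.10), and CDKN1A, the cell cycle inhibitor p21, from 65.3 ± 1.92 to 585 ± 11.2 TPM (3.14 ± 0.06, adjusted p = 6.61e-19). CLDN14 (3.08), KLRC1 (2.99), CXCL10 (2.73), CD80 (2.72) and DRAM1 (2.64) also rose. SCD, which makes monounsaturated fatty acids, fell from 810 ± 6.81 to 103 ± 2.67 TPM (-2.97 ± 0.04). CREG1 (-2.81), SSR1 (-2.74), LGALS1 (-2.49), PSPH (-2.47), ALDH1L2 (-2.46), and the mitotic genes AURKA (-2.40) and MAD2L1 (-2.33) fell. Against untreated cells ALDH1L2 stood at 0.04 and PSPH at -0.34, as the control knockdown lay above them. MYC fell by 0.88 (SE 0.03), IRF4 by 0.48 (SE 0.04) and PBRM1 by 0.39 (SE 0.06), though IRF4 did not pass against untreated cells (-0.05). CRBN did not pass (-0.06 ± 0.07), but was lower than in untreated cells (-0.25). In all, 7816 genes passed, 4152 higher and 3664 lower, with 235 and 400 at least 2-fold, but with median-of-ratios scaling 3826 were higher and 4022 lower.

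IKZF1 (0.14 ± 0.04, adjusted p = 0.011) and BRD7 (0.18 ± 0.06, adjusted p = 0.0104) also passed in the ARID2 knockdown. Both calls were lost without replicate 3 of the control knockdown (0.10 and 0.13), and that of BRD7 without replicate 3 of the ARID2 knockdown (0.145, adjusted p = 0.0539). Against untreated cells IKZF1 was lower by -0.13 and BRD7 did not pass (-0.015, adjusted p = 0.831).

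In the ARID2 knockdown the p53 list rose and mitotic genes fell. Of 29 p53 targets and CDK inhibitors 25 rose, 3 fell and 1 did not pass (median 1.03, adjusted p = 6.16e-12), with GADD45A at 1.81 and XPC at 1.30. All 60 G2/M genes fell (median -1.29, adjusted p = 2.41e-32), with CCNB1 at -1.86 and PLK1 at -1.59. S phase genes had 44 of 50 down, 1 up and 5 not passed (median -0.59, adjusted p = 2.63e-14), with CDC6 at -1.26. NF-kB targets had 17 of 23 up, 1 down and 5 not passed (median 0.54, adjusted p = 0.000215), with TRAF1 at 1.44 and NFKB2 at 0.59. Histone genes had 9 of 14 up and 5 not passed (10 up when adjusted over the list alone; median 0.98, adjusted p = 0.00452). Cholesterol genes had 22 of 24 down, 1 up and 1 not passed (median -0.95, adjusted p = 7.88e-13), with INSIG1 going from 588 to 123 TPM. Cytoskeletal genes had 27 of 42 down, 7 up and 8 not passed (8 up when adjusted over the list alone; median -0.25, adjusted p = 0.000235), though against untreated cells that list had adjusted p = 0.0702 with an estimated correlation. The mitochondrial share of TPM was higher in these libraries than in the control knockdown (18.5% against 17.2%).

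Secretory and stress lists fell in the ARID2 knockdown relative to a control that itself lay above untreated cells for both. Secretory genes had 31 of 35 down, 1 up and 3 not passed (median -0.50, adjusted p = 6.58e-15), with the translocon genes SSR1 at -2.74, SSR3 at -1.08 and SEC61B at -1.05. Against untreated cells 23 of these 35 genes were lower and 7 higher (median -0.26, adjusted p = 0.00398, but adjusted p = 0.249 with an estimated correlation). Integrated stress genes had 20 of 26 down, 2 up and 4 not passed (median -1.16, adjusted p = 1.06e-08), with ATF4 falling from 975 to 387 TPM (465 TPM in untreated cells). Against untreated cells 17 of these 26 genes were higher and 6 lower (median 0.32, adjusted p = 0.0109, but adjusted p = 0.249 with an estimated correlation). MYC targets had 28 of 54 down, 7 up and 19 not passed (median -0.16, adjusted p = 0.000465, but adjusted p = 0.109 with an estimated correlation). The control knockdown lay below untreated cells for this list, and against untreated cells 48 of the 54 genes were lower (median -0.53, adjusted p = 7.31e-13, and 0.00364 with an estimated correlation). Antigen presentation had 17 of 23 up, 5 down and 1 not passed (median 0.47, adjusted p = 0.00052, but adjusted p = 0.166 with an estimated correlation). HLA-DRA rose from 367 to 842 TPM. The list's median against untreated cells was 0.14 (adjusted p = 0.0288, but adjusted p = 0.326 with an estimated correlation). Interferon-stimulated genes had 21 of 44 up, 6 down and 17 not passed (median 0.26, adjusted p = 0.0213, but adjusted p = 0.205 with an estimated correlation), and against untreated cells 30 up and 4 down (median 0.43, adjusted p = 6.99e-05, and 0.0296 with an estimated correlation). Oxidative phosphorylation had 43 of 73 up, 9 down and 21 not passed (median 0.16, adjusted p = 0.00452, but adjusted p = 0.454 with an estimated correlation). It did not pass against untreated cells (adjusted p = 0.243). Of the 4 PBAF genes, ARID2 among them, 2 fell, 1 rose and 1 did not pass (median -0.25, adjusted p = 0.254). HBB rose from 15.2 to 27.8 TPM.

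The libraries labelled Aiolos knockdown, in which the IKZF3 transcript was higher, were compared with the control knockdown. IRF4 fell from 631 ± 10.9 to 137 ± 8.31 TPM (-2.20 ± 0.04, adjusted p = 4.35e-20). Among the largest falls were those of HRASLS2 (-4.57), ALDH1L2 (-4.14), CHAC1 (-3.73), PSAT1 (-3.26), SLC6A9 (-3.23), ARHGAP9 (-3.17), SLC7A11 (-3.10) and SLC7A5 (-3.04), all of them genes that the control knockdown held above untreated cells. PSAT1 stood at 89.3 TPM in untreated cells, 359 TPM in the control knockdown and 36.5 TPM in the labelled libraries, ALDH1L2 at 10.1, 62.0 and 2.59 TPM, HRASLS2 at 11.6, 39.2 and 0.697 TPM, and SLC7A5 at 126, 217 and 25.6 TPM. Against untreated cells the values were smaller: HRASLS2 -2.86, SLC7A5 -2.26, ALDH1L2 -1.64, PSAT1 -1.27, SLC6A9 -1.04, SLC7A11 -0.45 and ARHGAP9 -0.37, while CHAC1 was at the untreated level (0.00, adjusted p = 0.987). MME rose from 10.8 ± 0.648 to 165 ± 11.9 TPM (3.82 ± 0.08), and the sodium channel subunit SCNN1G from 102 ± 6.33 to 1033 ± 15.1 TPM (3.33 ± 0.04). KRT15 (4.53), FRMD3 (4.07), PON1 (3.26), BRINP2 (3.20) and SLC7A8 (3.00) also rose. CEMP1 (3.55 ± 0.90) overlaps a neighbouring gene and is uncertain. MYC fell by 0.18 (SE 0.03), and against untreated cells by 0.55. In all, 8522 genes passed, 4669 higher and 3853 lower, with 521 and 391 at least 2-fold, but 4179 were higher and 4415 lower with median-of-ratios scaling, and 4204 and 4236 with quantile normalization.

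Some small changes of fixed genes in the libraries labelled Aiolos knockdown rested on single libraries or on scaling. ARID2 was lower by -0.17 ± 0.07 (adjusted p = 0.0298), a call lost without any 1 of the control libraries (-0.16, -0.175 and -0.18 without replicates 1, 2 and 3) or without replicate 2 of the labelled libraries (-0.10), though ARID2 was also lower than in untreated cells (-0.38). IKZF1 was higher by 0.13 ± 0.04 (adjusted p = 0.016), lost without control replicate 3 (0.09), without replicate 3 of the labelled libraries (0.095) and under both other scalings (0.06 and 0.09), and turned against untreated cells (-0.14). CRBN was higher by 0.23 ± 0.07 (adjusted p = 0.0117), lost without control replicate 2 (0.18), with quantile normalization (0.14) and against untreated cells (0.04). BRD7 (0.10 ± 0.06) did not pass, but did without replicate 2 of the labelled libraries (0.14, adjusted p = 0.045), and PBRM1 (0.09 ± 0.06) did not pass.

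Stress, replication and glycolytic lists fell in the libraries labelled Aiolos knockdown. Integrated stress genes had 24 of 26 down and 2 not passed (median -1.43, adjusted p = 2.25e-15), but the list did not pass against untreated cells (median -0.16, adjusted p = 0.0679). Secretory genes had 33 of 35 down, 1 up and 1 not passed (2 up when adjusted over the list alone; median -0.73, adjusted p = 1.29e-16), with HERPUD1 at -1.43 (-0.35 against untreated cells) and FKBP11 at -1.85. Against untreated cells, below the control for this list, 25 of the 35 genes were lower and 6 higher (median -0.36, adjusted p = 9.08e-06, but adjusted p = 0.07 with an estimated correlation). S phase genes had 49 of 50 down and 1 not passed (median -0.95, adjusted p = 8.20e-23), with MCM6 at -1.77. G2/M genes had 54 of 60 down, 2 up and 4 not passed (55 down when adjusted over the list alone; median -0.48, adjusted p = 4.38e-12). MYC targets had 46 of 54 down and 8 not passed (1 up when adjusted over the list alone; median -0.40, adjusted p = 4.38e-12), and against untreated cells 53 of 54 down (median -0.78). Cholesterol genes had 21 of 24 down, 1 up and 2 not passed (median -0.59, adjusted p = 5.82e-08). Glycolysis had 17 of 22 down, 4 up and 1 not passed (median -0.50, adjusted p = 1.59e-05), with PDK1 at -1.41. Plasma cell transcription factors had 12 of 17 down, 3 up and 2 not passed (median -0.30, adjusted p = 0.000471), with CREB3L2 at -1.59 (-0.83 against untreated cells) and XBP1 at -0.74. Against untreated cells the G2/M, cholesterol and plasma cell transcription factor lists passed downward at the preset correlation (adjusted p = 1.52e-09, 0.00288 and 0.0131), but each had adjusted p = 0.07 with an estimated correlation.

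Targets of p53 and ribosomal protein genes rose in the same libraries. The p53 list had 24 of 29 genes up, 2 down and 3 not passed (median 0.54, adjusted p = 2.85e-06), with PLK2 at 1.55 and FAS at 1.37, and its median against untreated cells was 1.01. Ribosomal protein genes had 71 of 73 up, 1 down and 1 not passed (median 0.36, adjusted p = 3.83e-16, but adjusted p = 0.185 with an estimated correlation), with RPL13A at 0.77. Oxidative phosphorylation had 55 of 73 down, 6 up and 12 not passed (median -0.29, adjusted p = 3.80e-11, but adjusted p = 0.0584 with an estimated correlation). Interferon-stimulated genes had 24 of 44 up, 9 down and 11 not passed and the list did not pass (median 0.31, adjusted p = 0.0664), though it did with median-of-ratios scaling (adjusted p = 0.0353). Of the erythroid genes HBB fell from 15.2 to 4.01 TPM and EPOR from 9.95 to 4.47 TPM.

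**Figure D3:**
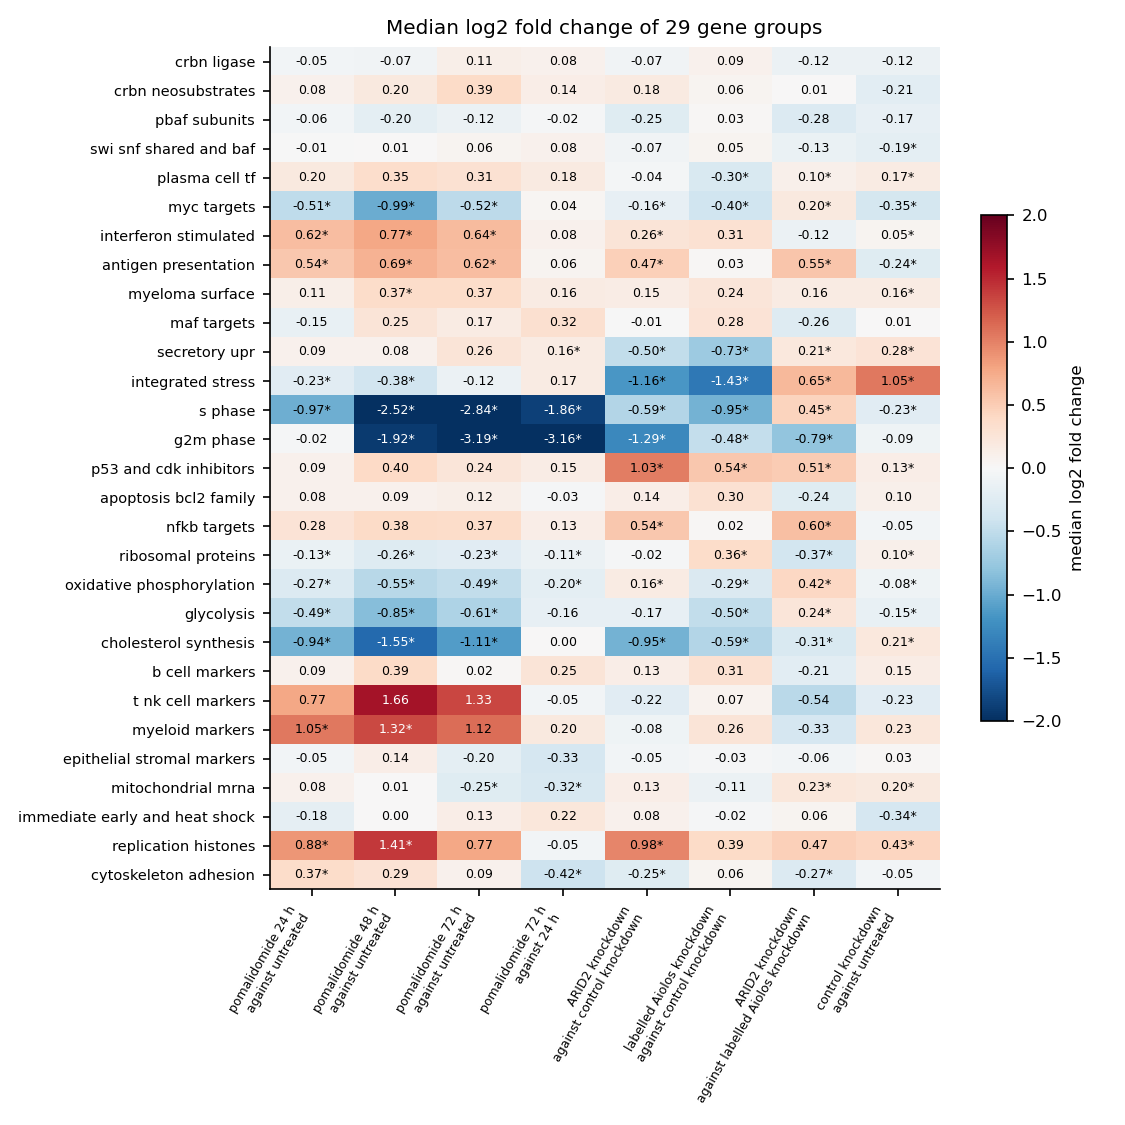
Median log2 fold change (colour and number) of the 29 gene lists with a list test (vertical axis) in 8 comparisons (horizontal axis), with a star where camera passed at the preset correlation. The integrated stress list was at -1.16 in the ARID2 knockdown and at -1.43 in the libraries labelled Aiolos knockdown against the control knockdown, which itself lay at 1.05 against untreated cells; stars mark tests before the estimated correlation, and small medians change sign with scaling.

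The ARID2 knockdown and the libraries labelled Aiolos knockdown, in which the IKZF3 transcript was higher, were then compared directly. HRASLS2 (3.91), the WNT inhibitor DKK1 (3.49) and FDXR (2.69) were higher in the ARID2 knockdown, as was TMEFF1 (3.03 ± 0.34), which is uncertain. MME (-5.09), KRT15 (-3.83), FRMD3 (-3.69) and CREG1 (-3.39) were higher in the libraries labelled Aiolos knockdown. IRF4 was higher in the ARID2 knockdown by 1.72 ± 0.04, whereas MYC (-0.70 ± 0.03), PBRM1 (-0.48 ± 0.06) and CRBN (-0.29 ± 0.07) were lower, and ARID2 itself lay at -0.84 ± 0.07. IKZF3 was lower by -0.12 ± 0.05 (adjusted p = 0.0395). Its call was lost without replicate 1 or 2 of the ARID2 knockdown (-0.11 and -0.11), without replicate 3 of the labelled libraries (-0.05) and under both other scalings. In all, 8282 genes passed, 3798 higher and 4484 lower, with 334 and 500 at least 2-fold, but with quantile normalization 4248 were higher and 4061 lower.

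The lists that differed between the ARID2 knockdown and the labelled libraries were read next. G2/M genes had 58 of 60 lower in the ARID2 knockdown, 1 higher and 1 not passed (median -0.79, adjusted p = 1.38e-15). S phase genes had 36 of 50 higher, 5 lower and 9 not passed (37 higher when adjusted over the list alone; median 0.45, adjusted p = 7.05e-09), with PCNA at 1.24. The p53 list had 18 of 29 higher, 9 lower and 2 not passed (median 0.51, adjusted p = 0.00226), with CDKN1A at 2.67. NF-kB targets had 14 of 23 higher, 6 lower and 3 not passed (median 0.60, adjusted p = 0.0153), with RELB at 0.98. CCL3, at 7951 against 580 TPM, shares reads with CCL3L3 and is uncertain. Integrated stress genes had 23 of 26 higher, 1 lower and 2 not passed (median 0.65, adjusted p = 4.13e-09). Oxidative phosphorylation had 69 of 73 higher, 1 lower and 3 not passed (70 higher when adjusted over the list alone; median 0.42, adjusted p = 4.79e-19). Ribosomal protein genes had 70 of 73 lower, 1 higher and 2 not passed (median -0.37, adjusted p = 2.23e-17, but adjusted p = 0.176 with an estimated correlation). Mitochondrial mRNAs had 10 of 13 higher and 3 not passed (median 0.23, adjusted p = 0.000868, but adjusted p = 0.353 with an estimated correlation and 0.125 with quantile normalization).

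Further lists passed in this comparison at the preset correlation alone. Plasma cell transcription factors had 9 of 17 higher, 6 lower and 2 not passed (median 0.10, adjusted p = 0.0383, but adjusted p = 0.176 with an estimated correlation), with XBP1 at 1.14 and PRDM1 at 1.33. Antigen presentation had 14 of 23 higher, 6 lower and 3 not passed (7 lower when adjusted over the list alone; median 0.55, adjusted p = 0.00539, but adjusted p = 0.24 with an estimated correlation). MYC targets had 32 of 54 higher, 5 lower and 17 not passed (median 0.20, adjusted p = 2.94e-05, but adjusted p = 0.0672 with an estimated correlation). Cholesterol genes had 18 of 24 lower, 3 higher and 3 not passed (19 lower when adjusted over the list alone; median -0.31, adjusted p = 0.00406, but adjusted p = 0.106 with an estimated correlation), with LSS at -1.30. Secretory, glycolysis and cytoskeletal lists also lost their calls, at adjusted p = 0.306, 0.176 and 0.176 with an estimated correlation.

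The drug effect was set across genes beside the ARID2 knockdown and the labelled libraries, each against the control knockdown. Between the drug at 72 h and the ARID2 knockdown, Pearson r over 12559 genes was 0.351, Spearman rho 0.326 and the covariance 0.156, where simulated libraries without effects gave a covariance of 8e-05. Of the calls, 2644 genes rose in both (1999.1 for independent lists) and 1857 fell in both (1158.2), while 1201 rose with the drug and fell with the knockdown (1764.2) and 834 did the opposite (1312.5). With the libraries labelled Aiolos knockdown r was 0.487, rho 0.525 and the covariance 0.252 (simulated -7e-05). Here 3437 genes rose in both (2248.1 for independent lists) and 2369 fell in both (1218), against 853 and 560 in opposite directions. At 24 h r was lower, at 0.190 with the ARID2 knockdown and 0.371 with the labelled libraries, and at 48 h it was 0.332 and 0.484. Covariances at 24 h were 0.0527 and 0.120. MME, MYB and SLC7A8 moved the same way with the drug and in the libraries labelled Aiolos knockdown, MYB standing at 26.9 TPM in untreated cells, 0.834 TPM at 72 h of drug, 12.6 TPM in the control knockdown and 3.96 TPM in the labelled libraries. The ARID2 knockdown and the labelled libraries shared their control libraries: r was 0.484 (simulated 0.503), and the covariance 0.137 (simulated 0.00866), a difference of 0.128. In that pair 2537 genes rose in both (1543.6 for independent lists) and 2108 fell in both (1124.1). The 3 control libraries cannot be divided into sets of at least 2, so part of the excess of these overlaps may come from the shared controls. The simulation holds only the spread between libraries, not the control knockdown's difference from untreated cells (5739 genes), which enters both effects. How much of the 0.128 lies beyond the shared control thus cannot be told. The control's part in r and the overlaps with the drug was not tested. The drug times shared the untreated libraries: r was 0.870 for 24 and 48 h, 0.767 for 24 and 72 h and 0.935 for 48 and 72 h (simulated 0.499 to 0.503).

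**Figure D4:**
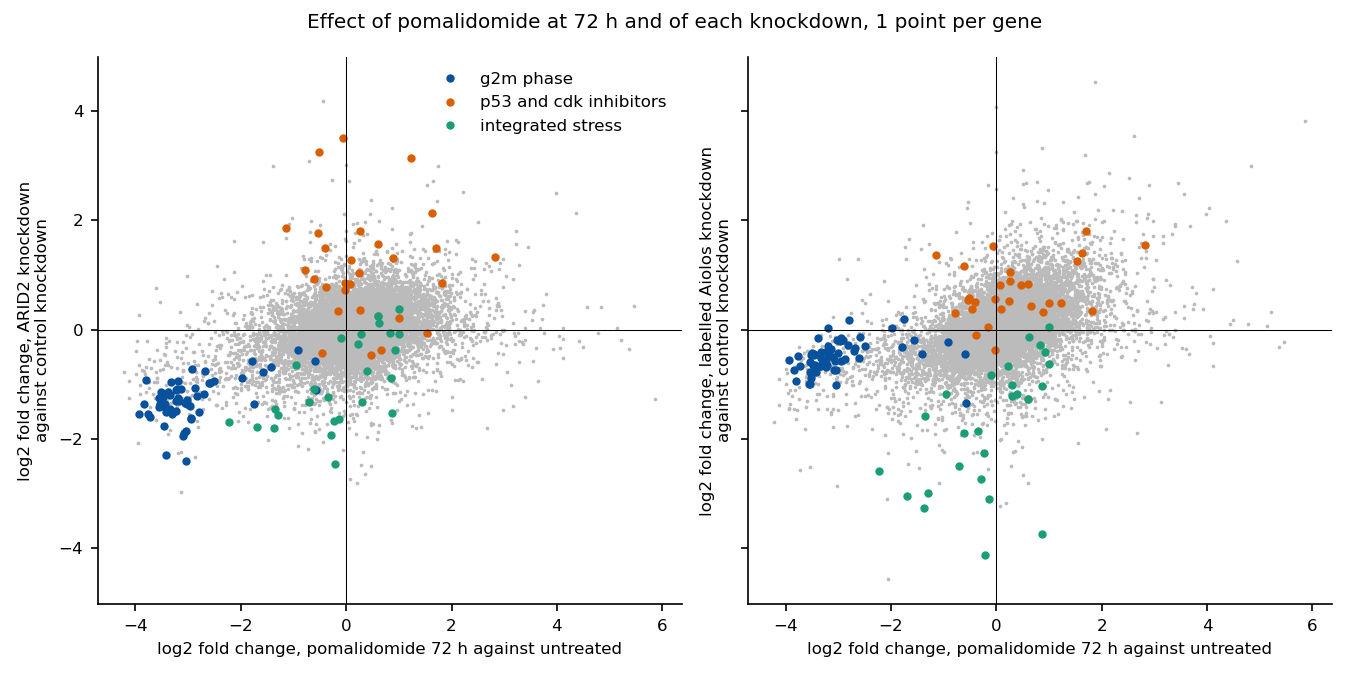
Log2 fold change of each gene with pomalidomide at 72 h against untreated cells (horizontal axis) and in the ARID2 knockdown or the labelled libraries against the control knockdown (vertical axes), 1 point per gene, with 3 lists coloured. Across genes r was 0.351 for the ARID2 knockdown (left) and 0.487 for the libraries labelled Aiolos knockdown (right), in which the IKZF3 transcript was higher.

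Genes that responded differently to the drug and to the ARID2 knockdown were tested as a difference of effects. MME differed most (7.14 ± 0.11), rising with the drug and standing at 10.8 TPM in the control and 3.89 TPM in the ARID2 knockdown. LAMB3 (5.73), LGALS3BP (5.41) and MMP9 (5.12) followed. KLRC1 (-4.38), SPARC (-4.37), MYB (-4.19) and the uncertain TMEFF1 (-4.04) lay on the other side, with SPARC going from 69.5 to 4.78 TPM with the drug and from 38.1 to 65.1 TPM with the knockdown. Of the fixed genes ARID2 (1.00 ± 0.09), IKZF1 (0.53 ± 0.06), PBRM1 (0.30 ± 0.08), IRF4 (-0.55 ± 0.05), IKZF3 (-0.34 ± 0.07) and BRD7 (-0.31 ± 0.08) passed. MYC (0.23 ± 0.04) and CRBN (0.33 ± 0.11) passed too but not with median-of-ratios scaling (0.10 and 0.21). Each effect was taken from its own control, and the control knockdown itself differed from untreated cells. With untreated cells as the control of both, IKZF3 (-0.10, adjusted p = 0.068) and BRD7 (-0.12, adjusted p = 0.0549) did not pass, while IRF4 became -0.98, MYC 0.60, IKZF1 0.80 and CRBN 0.52. In all, 8731 genes passed, 5079 higher and 3652 lower, but with median-of-ratios scaling 4250 were higher and 4439 lower. That scaling moved the median of all genes by -0.12, so medians are given relative to it. S phase genes lay lower with the drug (49 of 50, relative median -2.20, adjusted p = 1.39e-30), as did G2/M genes (58 of 60 lower, 1 higher, relative median -1.95, adjusted p = 3.48e-27). The p53 list had 20 of 29 lower and 7 higher (relative median -0.88, adjusted p = 0.000158). Secretory genes had 30 of 35 higher and 4 lower (relative median 0.79, adjusted p = 7.06e-09), beside a control knockdown at 0.28 against untreated cells. With untreated cells as the control of both, the relative median was 0.48 (adjusted p = 8.61e-05, but adjusted p = 0.162 with an estimated correlation). Oxidative phosphorylation (67 of 73 lower, relative median -0.69, adjusted p = 3.46e-18) and MYC targets (37 of 54 lower, relative median -0.49, adjusted p = 9.18e-08) also passed. The MYC target list lay at -0.35 in the control knockdown, and with untreated cells as the control of both it did not pass (21 lower and 22 higher, relative median -0.18, adjusted p = 0.12). Integrated stress, ribosomal protein, glycolysis and mitochondrial lists lost their calls, at adjusted p = 0.136, 0.579, 0.201 and 0.579 with an estimated correlation. From untreated cells the integrated stress list turned, with 18 of 26 lower with the drug and 6 higher (relative median -0.60, adjusted p = 0.000452, but adjusted p = 0.162 with an estimated correlation). Glycolysis did not pass (adjusted p = 0.0513), and cholesterol genes passed downward (adjusted p = 0.000803, but adjusted p = 0.0897 with an estimated correlation).

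The same difference was taken for the libraries labelled Aiolos knockdown, in which the IKZF3 transcript was higher. HSD11B1 (5.69 ± 0.21), LAMB3 (5.68 ± 0.32), MMP9 (5.07) and LGALS3BP (4.89) rose with the drug beyond the labelled libraries. DDAH1 (-4.27), FRMD3 (-4.07), NPPC (-3.91) and CBLN2 (-3.75) lay on the other side, DDAH1 going from 33.6 to 3.40 TPM with the drug and from 22.1 to 55.4 TPM in the labelled libraries. IRF4 fell less with the drug (difference 1.17 ± 0.05) and MYC more (-0.47 ± 0.04). IKZF1 (0.54 ± 0.06) and IKZF3 (-0.46 ± 0.07) also passed. BRD7 also passed (-0.24 ± 0.08, adjusted p = 0.0134). With untreated cells as the control of both, IRF4 became 0.75, MYC -0.10, IKZF3 -0.22 and IKZF1 0.81, and BRD7 did not pass (-0.05, adjusted p = 0.455). CRBN (0.04 ± 0.11), ARID2 (0.16 ± 0.09) and PBRM1 (-0.18 ± 0.08) did not pass. ARID2 passed without untreated replicate 1 (0.22) or without replicate 3 of the labelled libraries (0.22), and PBRM1 without replicate 2 of the labelled libraries (-0.23) and under both other scalings (-0.28 and -0.24). From untreated cells ARID2 (0.37, adjusted p = 6.21e-05) and CRBN (0.23, adjusted p = 0.00926) also passed. In all, 7907 genes passed, 4393 higher and 3514 lower, but with median-of-ratios scaling 3670 were higher and 4211 lower. G2/M genes had 59 of 60 lower with the drug and 1 higher (median -2.68, adjusted p = 2.76e-37), and S phase genes 48 of 50 lower (median -1.86, adjusted p = 4.93e-29). Integrated stress genes had 25 of 26 higher (median 1.52, adjusted p = 2.79e-12), beside a control knockdown at 1.05 against untreated cells, and the list did not pass with untreated cells as the control of both (median 0.33, adjusted p = 0.44). Secretory genes had 32 of 35 higher (33 when adjusted over the list alone) and 1 lower (median 0.91, adjusted p = 2.49e-15), with a median of 0.58 from untreated cells (adjusted p = 4.31e-08). Plasma cell transcription factors had 12 of 17 higher and 3 lower (median 0.73, adjusted p = 0.000738), and cholesterol genes 18 of 24 lower and 3 higher (4 higher when adjusted over the list alone; median -0.47, adjusted p = 0.000152). Ribosomal protein, antigen presentation, MYC target and oxidative phosphorylation lists lost their calls, at adjusted p = 0.0985, 0.175, 0.189 and 0.417 with an estimated correlation. From untreated cells MYC targets pointed up without passing (median 0.21, adjusted p = 0.511). The p53 list, which had not passed (18 of 29 lower, 8 higher, median -0.29, adjusted p = 0.0771), passed downward (median -0.60, adjusted p = 6.23e-05). So did mitochondrial mRNAs (adjusted p = 0.000447, but adjusted p = 0.564 with an estimated correlation).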

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

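The tests of explanations and the counts of other splits in this part were chosen only after the result was seen, whereas the scalings, the leaving out of libraries and the differences between groups were fixed before.

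The IKZF3 transcript was higher in the libraries labelled Aiolos knockdown. Swapped labels of these and the control knockdown libraries cannot be decided. In the libraries labelled Aiolos knockdown 11.09 times as many genes changed at least 2-fold against untreated cells. Distance from untreated cells does not show which libraries carry the hairpin, and that of the control is not given. IKZF3 in the control knockdown lay at -0.24 against untreated cells, a direction that a swap would also give. Low IKZF3 in the control knockdown is excluded as the whole cause, with 0.42 on the log2 scale against untreated cells, and scaling is excluded, with 0.60 as the lower of 2 scalings. A rise of the transcript that comes with loss of the protein cannot be told from these data: IKZF3 also rose by 0.55 in the ARID2 knockdown, and the protein was not measured here.

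The integrated stress list was lower in the ARID2 knockdown and in the libraries labelled Aiolos knockdown than in the control knockdown. A control knockdown above untreated cells fits, as the list's median against untreated cells was 0.32 in the ARID2 knockdown and -0.16 in the libraries labelled Aiolos knockdown. For the ARID2 knockdown a single control library is excluded, since its highest median without 1 control library was -1.14. Between these 2 sets of libraries the list's median differed by 0.65, in a comparison that does not use the control. A raised control alone thus does not account for the difference between them. The part of each hairpin in the list's level cannot be told apart, with the control knockdown at 1.05 against untreated cells. The cause was not tested.

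The p53 and CDK inhibitor list was higher in the ARID2 knockdown. Transduction and a hairpin in general cannot be decided as a cause. The rise was not equal in both sets of libraries, with a median difference of 0.51 from the libraries labelled Aiolos knockdown. Whether the amount of virus or the general effect of a hairpin was equal is not given in the sources used here. The list also rose in those libraries against the control knockdown, so the rise was shared in part. Whether lower expression of cell cycle genes in itself raised the list cannot be decided. The list's unshifted median with the drug at 72 h was 0.24, but many other genes also changed with the drug. Scaling is excluded, with 0.99 as the lower of 2 scalings. The cause was not tested.

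Between 72 and 24 h of drug the medians of S phase, G2/M and cytoskeletal genes differed by -1.86, -3.16 and -0.42. IRF4 differed by 0.64 and CRBN by 0.32. IKZF1 differed by 0.14 and MYC by 0.18, calls lost with median-of-ratios scaling (0.028 and 0.07), and that of IKZF1 also with quantile normalization (0.043) and without replicate 1 of the 72 h group (0.102). Of 260 other named genes 210 differed. Between the ARID2 knockdown and the libraries labelled Aiolos knockdown, in which the IKZF3 transcript was higher, the medians differed by 0.65 for integrated stress, 0.45 for S phase, -0.79 for G2/M, 0.51 for p53, 0.60 for NF-kB and 0.42 for oxidative phosphorylation genes. ARID2 differed by -0.84, MYC by -0.70, IRF4 by 1.72, CRBN by -0.29 and PBRM1 by -0.48, and of the 260 other named genes 233 differed. IKZF3 differed by -0.12, a call lost under 8 settings, among them both other scalings (-0.087 and -0.096) and leaving out replicate 3 of the labelled libraries (-0.054).

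The 3 libraries of each of 2 groups can be divided in 10 ways, too few for a share under 0.05. For the 2 differences of effects only the 72 h libraries and those of the ARID2 knockdown or of the libraries labelled Aiolos knockdown were exchanged, each after its own control mean was taken away, and the controls stayed in place. In each of the 10 comparisons only 1 of the 10 splits, the real one, gave as many changed genes. Every other split mixes the 2 real groups, so their difference enters the fitted spread. Low counts then follow for any strong comparison, and they say nothing about chance. The highest count of any other split was 1 gene for 24 h of drug (8301 in the real split), 1 for 72 against 24 h (8140) and 2 for the control knockdown against untreated cells (5739). It was 0 for 48 h (9880), 72 h (10017), the ARID2 knockdown (7816), the libraries labelled Aiolos knockdown (8522), the ARID2 knockdown against the labelled libraries (8282), and the differences of the drug effect from the ARID2 knockdown (8731) and from the labelled libraries (7907).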

How the results depend on the processing

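The comparison with untreated libraries and the correlations without the cell cycle, MYC target and histone lists were chosen only after the result was seen.

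The correlation of the drug at 72 h with the ARID2 knockdown, 0.351, was 0.298 with a pseudocount of 0.1, 0.345 without the filter, 0.369 with a filter of 5 TPM, 0.336 with quantile normalization and 0.310 without those lists. For the libraries labelled Aiolos knockdown, in which the IKZF3 transcript was higher, 0.487 became 0.447 with the pseudocount of 0.1, 0.501 with the filter of 5 TPM, 0.476 with quantile normalization and 0.474 without those lists. Leaving out 1 library gave from 0.480 to 0.489. Between the ARID2 knockdown and the labelled libraries, 0.484 became 0.472 with quantile normalization and 0.476 without those lists, and leaving out 1 library gave from 0.477 to 0.491.

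Of 290 list tests, 118 passed with the preset correlation, 67 with an estimated correlation and 249 with fry. With fry the BCL2 family passed upward for the drug at 72 h (adjusted p = 1.65e-10) and for its difference from the ARID2 knockdown (adjusted p = 0.000377), and interferon-stimulated genes passed upward between 72 and 24 h (adjusted p = 0.000687), where camera pointed down without passing. Against untreated cells the ARID2 knockdown had the integrated stress list (adjusted p = 0.0109, but adjusted p = 0.249 with an estimated correlation) and ribosomal protein genes (adjusted p = 0.00379, but adjusted p = 0.56 with an estimated correlation) upward. With untreated cells as the control of both effects, integrated stress genes were lower with the drug than in the ARID2 knockdown (adjusted p = 0.000452, but adjusted p = 0.162 with an estimated correlation). MYC targets pointed up beside the labelled libraries without passing (adjusted p = 0.511).

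Among named genes, ALDH1L2 was 0.036, IKZF1 -0.131 and BRD7 -0.015 in the ARID2 knockdown against untreated cells, and IKZF1 was -0.141 in the libraries labelled Aiolos knockdown. MT-CO1 was -0.063 between the ARID2 knockdown and the labelled libraries with quantile normalization. Of 578 pairs of gene and comparison, 558 kept their call with median-of-ratios scaling and 562 with quantile normalization.

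With the replicate number as a block, 577 of the 578 pairs and all 290 list tests kept their call. The number gave no sign of pairing: 2 of 21 libraries were closest to libraries of their own number, and correlations of pairs ran from -0.125 to 0.076.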

Other observations

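All comparisons in this part were chosen only after the result was seen.

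Actin genes were read over the drug times, which have no untreated cells of their own. ACTG1 stood at 1426 ± 22.1 TPM in untreated cells (SD, n = 3), 2909 ± 63.6 at 24 h, 1198 ± 38.9 at 48 h and 358 ± 12 at 72 h. ACTB stood at 2371 ± 12.7, 3549 ± 89.4, 1669 ± 39.4 and 847 ± 24.7 TPM. HMOX1, in contrast, stood at 23.3 ± 1.15, 45.1 ± 2.39, 71.1 ± 4.86 and 508 ± 143 TPM, and was also higher in the ARID2 knockdown (89.2 ± 4.96) than in the control knockdown (19.6 ± 0.559).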
